A study of Mus musculus with 15 samples.

How the data were processed

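The deposit holds single-cell RNA sequencing of intestinal cells from 5 mice, each sampled in the proximal small intestine, the distal small intestine and the colon, which gives 15 samples. Per the labels, the mice were 6 months old, carried the Lgr5-eGFP-IRES-CreERT2 allele, which marks Lgr5-expressing stem cells with a green fluorescent protein, and ate a control diet with 10% of kcal from fat (2 mice) or a high fat diet with 60% of kcal from fat (3 mice). Libraries were made with Seq-Well with second strand synthesis, a method that isolates single cells in small wells, per the labels' protocols. Each deposited value is a raw count of unique molecular identifiers (UMIs) per gene and cell: all values were whole numbers, and their sums equalled the total UMI count that the authors' cell table gives for every cell. The genome build was mm10 per the labels. The aligner, the counting tool and the gene annotation are not stated.

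The authors had filtered the cells before deposit. The table holds 17185 genes and 18919 cells, 8622 from the control diet and 10297 from the high fat diet. The lowest cell had 538 UMIs and 492 genes, and the mitochondrial share reached 35.0% and no more. No filter on cells was added. The values look as if most rarely seen genes had been removed within each library, a step that no label records. Summed over the 15 libraries, 47183 gene entries had no count in any cell of the library, while only 94, 248, 682 and 1839 were seen in 1, 2, 3 and 4 cells and 5035 in 5 cells. A 0 in a library was therefore taken to give no limit on a gene's level, and no lower bound on a fold change was computed from it. A count was present in every library for 11159 genes.

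The authors' cell table gives the diet, organ and mouse of each cell and a call of stem or not stem. The call equalled at least 1 UMI of Lgr5 or of eGFP in every one of the 18919 cells, so Lgr5 is no finding within stem-called cells. The table numbers the control mice 1 and 3, while the sample titles number them 1 and 2, so its control mouse 3 was taken as control mouse 2 by elimination. The call also depends on depth, and cells that should lack Lgr5 carry it. Whether free RNA or cells caught together account for this was not tested. The call was carried by 8.69% of 967 T and B cells (median 4417 UMIs), which should lack Lgr5, against 25.3% of 17952 other cells (median 13674.5 UMIs). With every cell thinned to 3000 UMIs, the shares were 6.49% and 12.4%. In the proximal small intestine the T and B cells carried it more often, at 22.4% and 33.3% in control and 11.1%, 28.1% and 23.8% in high fat diet mice, against 36.8%, 32.1%, 19.2%, 17.4% and 18.2% of all cells. Within each small intestine library, 27 or 28 of 28 other genes of a fixed stem cell list were higher in called than in uncalled cells, and 24 or 25 of 28 in the colon libraries. The cells are therefore named stem-called cells.

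No cell types other than the stem call were deposited. In Python 3.11.15, cells were normalised to 10000 counts and log transformed, and 2000 variable genes were chosen over samples with scanpy 1.11.5 and scaled with values limited to 10. From 30 principal components, 15 neighbours per cell (scikit-learn 1.9.0) weighted by the neighbours they share gave the graph for the Leiden algorithm (leidenalg 0.10.2, python-igraph 0.11.9) at resolution 1, 5 iterations and seed 0. Marker genes of 15 types were fixed in advance. Each of the 30 clusters was named after the type ("-like") with most markers at 2 times or more the level in the other cells (10 CPM added to both), if at least 3 markers reached it. A cluster with more markers of another type among its 10 leading genes, or of shallow cells with no marker among them, was to stay without a name, but every cluster left unnamed had fewer than 3 markers. This naming rule was written after the cells had been clustered. The 8 clusters left without a name hold 6222 cells, 32.9% of all. They held 12.7% of control and 49.3% of high fat diet cells in the proximal small intestine, 20.9% and 18.4% in the distal small intestine, and 60.9% and 42.3% in the colon. Proximal crypt cells split by diet between clusters, so the shares of stem-like, transit-amplifying-like and absorptive-like cells were not compared. Scrublet called 242 doublets (1.28%), which were kept in the main analysis and removed in an alternative.

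Raw counts were summed per sample over stem-called cells, over transit-amplifying-like cells and over absorptive-like cells, leaving stem-called cells out of the last 2 populations. A sum needed at least 20 cells. Under that rule, the high fat diet mouse 1 gave no transit-amplifying sum in the proximal small intestine (13 cells), and the colon could not be tested in transit-amplifying cells (no such cluster) or absorptive cells (1 high fat diet sample left). Diet effects within an organ were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM normalisation, filterByExpr by group, R 4.3.3) in a model with 6 groups of diet and organ, so that all organs share 1 estimate of the spread. The mean of the diet effects over organs was tested with limma 3.58.1 (voom, duplicateCorrelation with the mouse as a random block); for transit-amplifying and absorptive cells it covers the proximal and distal small intestine. The samples of 1 mouse pair across organs, since they come from the same animal: their deviations from the group means over 5000 genes correlated at 0.224 to 0.828, and the estimated correlation was 0.385 in stem-called, 0.531 in transit-amplifying and 0.280 in absorptive cells. Organ differences and diet by organ interactions in stem-called cells were tested with edgeR with the mouse as a fixed block. All p-values are two-sided and adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Genes with no count in an organ have a fitted log2 fold change of 0 there (100 genes proximal, 24 distal and 106 colon of 12339 tested). Genes named for an organ difference had to differ in the same direction in all 5 mice. Levels are counts per 1e6 (CPM) of the summed counts with TMM factors, as mean ± SD over mice. Levels compared between organs are from counts pooled over the libraries of an organ, so deeper libraries weigh more. Levels compared between cell types are means over libraries. Neither of these has TMM factors. Fold changes are log2 of high fat over control diet, with the standard error (SE) given by the size of the change divided by the square root of F.

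The 24 gene lists were fixed before the data were examined, as were the groups, tests, cell type markers and the alternatives named first below. They cover PPAR targets and fatty acid oxidation, ketone body synthesis and use, lipid absorption and chylomicrons, lipogenesis, cholesterol synthesis, intestinal stem cell genes, Wnt targets, cell cycle, MHC class II, MHC class I, interferon response, antimicrobial defence, defensins, sugar uptake and glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, bile acid transport, dissociation stress, unfolded protein response, glutathione and xenobiotic defence, ribosomal proteins, proximal small intestine, distal small intestine and colon. Lists were tested with camera at a preset correlation of 0.01 (cameraPR for the mean over organs), and beside it with an estimated correlation and with fry, each adjusted over the 24 lists of a comparison. Genes named in the text follow a rule: the 10 higher and 10 lower genes with the largest change among called genes with a mean log2 CPM of at least 4 and no overlap between the mice of the diets (5 and 5 in transit-amplifying and absorptive cells), the 3 higher and 3 lower genes with the smallest p where none was called, up to 4 genes per list with the smallest p, and a set of lipid, stem cell and immune genes in stem-called cells. Of the genes these rules pick, 2 are not reported here, though the counts of called genes and the lists include them. Positions are from GENCODE mouse release M21 on mm10. Shares of cell types were compared with an exact permutation test over the 10 splits of 5 mice into 2 and 3, for which the smallest possible p is 0.1. The tables were handled with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9.

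The tests were checked on counts drawn from negative binomial distributions with the organ means, gene dispersions and totals of the stem-called sums, with 100 genes of more than 16 CPM changed at each fold, up or down. For the proximal diet effect in stem-called cells, edgeR recovered 36% of genes changed 2-fold and 92% of those changed 4-fold over 12133 genes, and 9 of its 137 calls were false. For the distal effect over 12082 genes it recovered 29% and 92%, with 7 of 128 calls false, and DESeq2 45% and 96%, with 20 of 161 false. The mean over organs in limma recovered 90% and 98%, the colon to proximal organ difference in edgeR 81% and 99% (11465 genes, all others drawn at 1 level), and the proximal to distal interaction 3% and 80% (12118 genes). Of the calls in these 3 tests, 15 of 203, 9 of 189 and 8 of 91 were false. In an unchanged organ edgeR called 0 genes. Each list test called a list raised 1.5-fold and 0 of the 23 other lists. Genes and libraries were drawn independently, without the correlation between the organs of a mouse, between genes or within a depth set. These rates may therefore be better than those in the real data, above all for the mean over organs and the lists.

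The libraries fall into 2 sets by depth that the labels do not explain. The 6 libraries of the mice that the cell table numbers 3 had lowest cells of 3672 to 8142 UMIs and medians of 15310 to 21609, and the 9 others lowest cells of 538 to 1793 and medians of 2723 to 13640.5. Each set holds both diets, so values within the sets are given beside the fitted ones as differences of mean log2 CPM with 0.5 CPM added (10 CPM where stated, which draws low levels toward 0), with 1 control and 1 high fat diet mouse in the deeper set and 1 control and 2 high fat diet mice in the shallower set. No p-value was computed within a set.

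Alternatives fixed in advance were DESeq2 size factors in edgeR, no filter on low counts, at least 50 cells per sum, removal of doublets, cells thinned to at most 1000 UMIs, the DESeq2 1.42.0 Wald test, limma voom, the samples of 1 organ only, a replicate block on the mouse numbers, other ways to average the organs, organ differences without the mouse block or within 1 diet, epithelial cells as the denominator, cells of at least 1000 UMIs, edgeR and the mean over organs for shares, and each mouse left out in turn. Added after seeing the data were the high fat diet proximal library of mouse 1 left out alone, a block on the cell table's numbers, depth set as a factor, genes with a count in all 15 libraries, stem-like clusters in place of the stem call, the stem call in epithelial clusters only, and the stem call made at 3000 UMIs in every cell. Not analysed were deposited sequence reads, which were not among the files, and differences between single cells, since cells of a mouse are not replicates.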

Results

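The series asks how a high fat diet, fed to 3 mice against 2 on a control diet, changes fatty acid oxidation and stem cell genes in the mouse intestine at single-cell resolution. The 15 samples differ in depth. In the proximal small intestine, the control mice 1 and 2 gave 1646 and 1920 cells (medians 12040.5 and 19980.5 UMIs) and the high fat diet mice 1 to 3 gave 1079, 1740 and 1667 cells (4757, 13640.5 and 15310 UMIs). In the distal small intestine the same mice gave 1080 and 1579 against 1016, 930 and 1890 cells (5569 and 21609 against 9388, 5431 and 16711.5 UMIs), and in the colon 1495 and 902 against 549, 324 and 1102 cells (4915 and 17839 against 5169, 2723 and 19473.5 UMIs). Stem-called cells numbered 606 and 617 against 207, 302 and 304 in the proximal small intestine, 231 and 565 against 354, 233 and 501 in the distal small intestine, and 279 and 113 against 79, 27 and 200 in the colon. Their summed counts ranged from 321496 to 13694552 UMIs per sample.

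In stem-called cells of the proximal small intestine, genes that burn fatty acids were higher and a gene that makes unsaturated fatty acids was lower on the high fat diet. In T-like cells of the same libraries, which are not epithelial, levels went the same way: Acot1 from 12.0 to 108 CPM, Creb3l3 from 3.99 to 200 CPM and Scd2 from 160 to 38.2 CPM. In those cells 3 of 6606 genes were called, all higher, with Creb3l3 among them and Scd2 not. The likeness of the 2 cell types was not tested. A response of the stem-called cells themselves was therefore not separated from free RNA. Acot1 and Acot2 release fatty acids from coenzyme A, Acadl dehydrogenates long-chain fatty acids in mitochondria, and Slc25a20 carries acylcarnitines into them. Creb3l3 encodes a transcription factor of fasting and lipid metabolism, Me1 makes NADPH, Mgll splits monoglycerides, and Scd2 desaturates fatty acids. edgeR called 15 of 12339 genes, 14 higher and 1 lower, and 459 had an unadjusted p under 0.05. The mice of the diets did not overlap for 17.7% of genes, where 2 of 10 splits give 20% by chance.

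The largest rise among called genes was that of Creb3l3 (log2 fold change 4.49, SE 0.39, adjusted p = 0.00013; 5.12 ± 0.628 CPM in 2 control mice against 115 ± 27.6 in 3 high fat diet mice; chromosome 10, 81084324 to 81098874). Me1 rose by 4.03 (SE 0.50, adjusted p = 0.00209; chromosome 9, 86581371 to 86695953) and Mgll by 3.97 (SE 0.43, adjusted p = 0.00113; 2.25 ± 1.40 against 34.5 ± 1.62 CPM; chromosome 6, 88724412 to 88828360). Acot1 rose from 20.1 ± 5.84 to 194 ± 67.6 CPM (adjusted p = 0.00351; chromosome 12, 84009490 to 84018371). Acot2 rose by 2.59 (SE 0.34, adjusted p = 0.00328) and Acadl by 1.82 (SE 0.22, adjusted p = 0.00209; 62.6 ± 2.01 against 221 ± 31.9 CPM; chromosome 1, 66830839 to 66863277). The other higher genes were Akr1b8, an aldehyde reductase (2.65, adjusted p = 0.0395), Aldh1a1, a retinal dehydrogenase (2.08, adjusted p = 0.0398), and Hsdl2, a peroxisomal dehydrogenase (adjusted p = 0.0348). Slc25a20 (1.73, adjusted p = 0.0103), the annexin Anxa13 (1.70, adjusted p = 0.0349) and the retinol saturase Retsat (adjusted p = 0.0157) were higher too, the last at 43.5 ± 1.86 against 114 ± 24.1 CPM. Anks6, a ciliary protein gene chosen after its values were seen, rose by 3.35 (adjusted p = 0.0013). The 1 lower gene was Scd2 (SE 0.32, adjusted p = 0.00328; 104 ± 22.7 against 19.4 ± 5.38 CPM; chromosome 19, 44293674 to 44306864).

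Within the deeper and the shallower set of mice, the log2 ratios were 4.04 and 4.36 for Creb3l3, and -1.86 and -2.87 for Scd2. Creb3l3 and Mgll stayed called whichever mouse was left out. Acot1, Acot2 and Acadl lost theirs without control mouse 1 (3.62, 2.61 and 1.80), control mouse 2 (2.97, 2.56 and 1.83) or high fat diet mouse 2 (3.27, 2.37 and 1.75). Me1 lost its call without either control mouse (4.03 and 4.01), and Scd2 without control mouse 1 (-2.17) or high fat diet mouse 2 (-2.20). Akr1b8 (2.33 to 2.93) and Aldh1a1 (1.94 to 2.20) lost theirs whichever mouse was left out, Hsdl2 (1.80 to 2.02) without any 1 high fat diet mouse, and Slc25a20 (1.51 to 2.00), Anxa13 (1.58 to 1.80) and Retsat (1.23 to 1.45) without any mouse but high fat diet mouse 3. The number of called genes fell to 6 without control mouse 1, 5 without control mouse 2 and 4 without high fat diet mouse 2, of which 5, 4 and 4 were among the 15, and to 9 without the proximal library of high fat diet mouse 1.

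**Figure D1:**
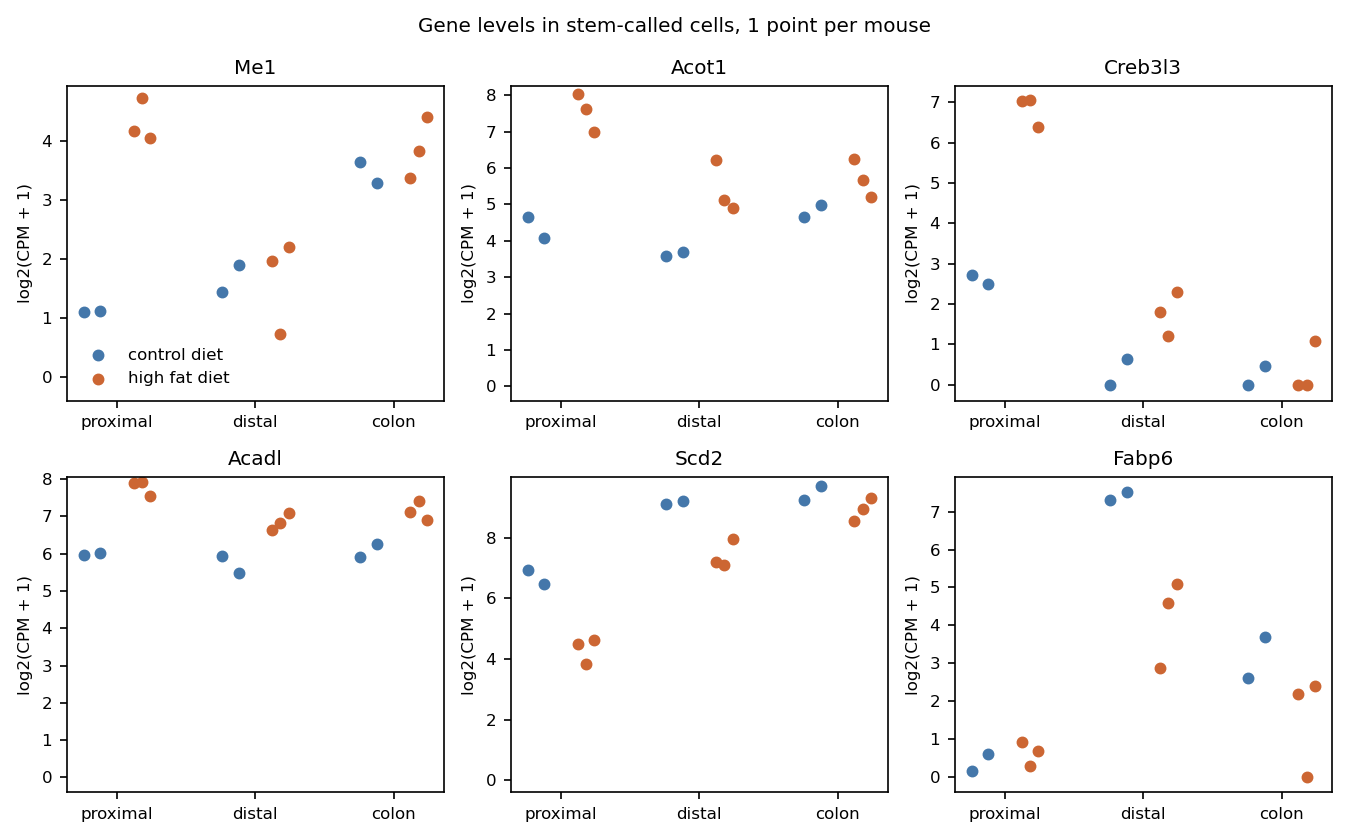
Levels of 6 genes in stem-called cells as log2(CPM + 1), with 1 point per mouse, by organ (horizontal) and diet (colour: blue control, orange high fat). Proximal Creb3l3 averages 5.12 CPM in control and 115 CPM in high fat diet mice, and the points of the diets do not overlap.

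Among the gene lists, PPAR targets and fatty acid oxidation genes rose as a group in proximal stem-called cells, as they did in T-like cells of the same libraries (median 0.81, adjusted p = 0.0159 with an estimated correlation). Of 47 genes, 7 were called, and 29 rose and 0 fell when adjusted over the list alone. The median log2 fold change was 0.65 (mean 1.29; adjusted p = 8.3e-71 and adjusted p = 0.00128 with an estimated correlation). The median was 0.734 and 0.702 within the deeper and shallower mice. The fatty acid importer Cpt1a of the same list was not called (1.38, adjusted p = 0.412; 187 ± 80.8 against 487 ± 36.4 CPM). Nor were the lipid carriers Fabp2 (1.65) and Fabp1 (5.02, adjusted p = 0.0587), though Fabp1 was called without high fat diet mouse 1 (4.52) or mouse 3 (5.23). The glutathione and xenobiotic defence list, which covers detoxifying enzymes, rose too (2 of 28 called, 5 rose over the list alone, median 0.64, adjusted p = 1.9e-17 and adjusted p = 0.00142 with an estimated correlation). Ketone body synthesis and use (median 0.13, adjusted p = 0.00524) and lipid absorption and chylomicrons (0.24, 0 of 22 called, 4 rose over the list alone, adjusted p = 9.5e-05) passed camera only, each at adjusted p = 0.0637 with an estimated correlation.

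The defensins, antimicrobial peptides of Paneth cells, fell in proximal stem-called cells (median -3.48 over 8 genes; 0 called, 6 fell over the list alone, adjusted p = 5.4e-18 and adjusted p = 0.0392 with an estimated correlation). Defensin genes are close paralogs, so single members are uncertain. The proximal libraries hold few Paneth-like cells, 4 and 7 in the control and 1, 7 and 5 in the high fat diet mice, with or without the stem call. The fall was -3.47 and -2.95 within the deeper and shallower mice, and the list's median was 0.72 when the stem call was made at 3000 UMIs in every cell. Much of the fall lies in stem-called cells of the Paneth-like cluster. Without them the log2 ratio of the diets (0.5 CPM added) went from -2.43 to -0.38 for Defa24, from -3.15 to -0.18 for Defa17 and from -4.40 to -1.43 for AY761184. These genes are among the leading genes of that cluster, so the drop does not show which cells express them. Lower by camera alone were MHC class II (-0.82, 4 of 10 fell over the list alone, adjusted p = 7.4e-07 and adjusted p = 0.170 with an estimated correlation) and antimicrobial defence (-0.44, or -1.14 over genes with a count, adjusted p = 0.000548 and adjusted p = 0.170 with an estimated correlation). So were Wnt targets (-0.18, adjusted p = 0.000147 and adjusted p = 0.0637 with an estimated correlation) and MHC class I (-0.10, adjusted p = 0.00524 and adjusted p = 0.0852 with an estimated correlation).

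The intestinal stem cell list was slightly lower by camera (median -0.10, 0 of 29 called, adjusted p = 0.00445 and adjusted p = 0.373 with an estimated correlation). The stem cell genes Olfm4 (0.14; 4571 ± 52.1 against 5024 ± 599 CPM) and Ascl2 (0.09) and the proliferation gene Mki67 (-0.20) were not called. Lgr5 cannot be judged within cells called on Lgr5 itself. The distal small intestine list was higher by camera (0.26, adjusted p = 0.0156 and adjusted p = 0.399 with an estimated correlation). Lists that did not pass were cholesterol synthesis (0.24, adjusted p = 0.0659), bile acid transport (0.48, adjusted p = 0.0780), dissociation stress (0.22, adjusted p = 0.151), unfolded protein response (0.09, adjusted p = 0.162) and ribosomal proteins (0.03, adjusted p = 0.94). Also without a call were cell cycle (-0.09, adjusted p = 0.471), sugar uptake and glycolysis (-0.04, adjusted p = 0.106), nuclear-encoded oxidative phosphorylation (-0.02, adjusted p = 0.574) and mitochondrially encoded genes (-0.18, adjusted p = 0.152). In 4 lists that did not pass, the signs part. They are lipogenesis (median -0.06, mean 0.33, test downward, adjusted p = 0.94) and interferon response (-0.08, mean 0.01, downward, adjusted p = 0.435). The other 2 are proximal small intestine (-0.10, mean 0.44, upward, adjusted p = 0.20) and colon (0, mean -0.21, upward, adjusted p = 0.94).

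**Figure D2:**
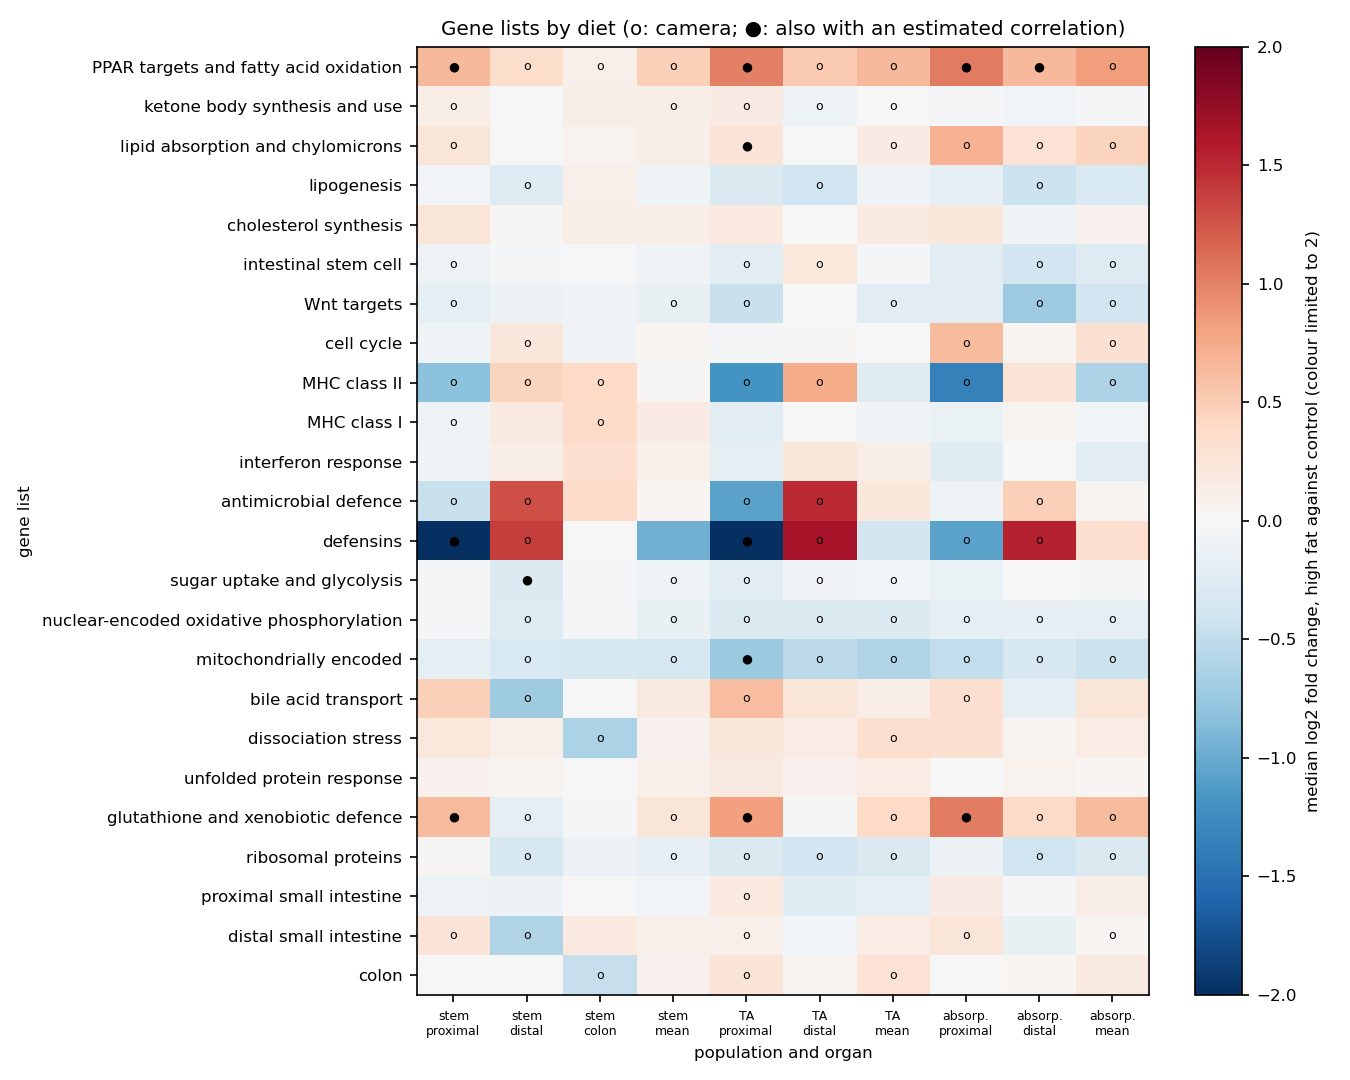
Median log2 fold change, high fat against control diet (colour, limited to 2 in either direction), of 24 gene lists (vertical) in stem-called, transit-amplifying (TA) and absorptive cells by organ (horizontal); open circles pass camera, filled circles also pass with an estimated correlation. The medians of PPAR targets and fatty acid oxidation are above 0 in every column, from 0.10 in colon stem-called cells to 1.03 in proximal absorptive cells.

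In stem-called cells of the distal small intestine, edgeR called 1 of 12339 genes (330 at an unadjusted p under 0.05), and 0 from the samples of that organ alone (246 of 11442 under 0.05), without control mouse 2 (785) or without high fat diet mouse 2 (272). Not called were Fabp6, the bile acid carrier of the ileum (-3.01, SE 0.47, adjusted p = 0.0824), Scd2 (-1.67, adjusted p = 0.164), and the lipid genes Acadl (1.17) and Mgll (2.34), each at adjusted p = 0.241. The mice did not overlap for 13.3% of genes, where chance gives 20%.

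Of the lists in distal stem-called cells, sugar uptake and glycolysis fell (median -0.27, 0 of 26 called, adjusted p = 4.8e-06 and adjusted p = 0.00888 with an estimated correlation). A median of this size was not particular to that list. It was -0.32 for ribosomal proteins, -0.31 for mitochondrially encoded genes and -0.26 for both nuclear-encoded oxidative phosphorylation and lipogenesis, while other lists had medians above 0. No value within the depth sets was computed for the glycolysis list. PPAR targets and fatty acid oxidation were higher by camera (0.35, or 0.358 and 0.382 in the deeper and shallower mice; 8 of 47 rose over the list alone, adjusted p = 7.3e-18 and adjusted p = 0.0521 with an estimated correlation). Camera alone also found antimicrobial defence higher (1.29, adjusted p = 5.6e-05 and adjusted p = 0.226 with an estimated correlation) and the distal small intestine list lower (-0.60, adjusted p = 5.6e-05 and adjusted p = 0.228 with an estimated correlation). The defensins were higher by camera (1.39, adjusted p = 0.0122 and adjusted p = 0.521 with an estimated correlation), at 2.44 in the deeper and -0.60 in the shallower mice, and lost the call without high fat diet mouse 3 (0.40). Without stem-called cells of the Paneth-like cluster, the distal log2 ratio of the diets (0.5 CPM added) went from 1.11 to 0.45 for Defa24. It went from 0.81 to 0.21 for Defa17 and from 1.00 to -0.02 for AY761184.

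In stem-called cells of the colon no gene was called. edgeR called 0 of 12339 genes, with 314 at an unadjusted p under 0.05. DESeq2 called 0 of 12316 (249 under 0.05) and limma voom 0 (227 under 0.05). The genes with the smallest p were Acadl (1.04; 66.8 ± 11.6 against 141 ± 25.5 CPM), the sorting nexin Snx7 (0.90) and the phosphatase Ptp4a3 (4.80 against 13.0 CPM) on the higher side. On the lower side they were the MAP kinase phosphatase Dusp6 (-1.84), the secretory factor Foxa3 (-1.27) and Uspl1 (-0.85). By camera, fatty acid oxidation genes and PPAR targets were higher (0.10, 0 of 47 called, 1 rose over the list alone, adjusted p = 0.000794 and adjusted p = 0.811 with an estimated correlation). The median was 0.158 and -0.034 in the deeper and shallower mice (10 CPM added), and the call was lost without control mouse 2 (-0.01, adjusted p = 0.975) or high fat diet mouse 1 (adjusted p = 0.106). The dissociation stress list, of immediate early genes, was lower by camera (-0.63, adjusted p = 1.6e-10 and adjusted p = 0.608 with an estimated correlation) but had a median of 0.50 without control mouse 2. MHC class I was higher by camera (0.39, adjusted p = 0.00109 and adjusted p = 0.226 with an estimated correlation).

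Averaged over the 3 organs, limma called 4 of 12339 genes in stem-called cells (380 at an unadjusted p under 0.05), 3 higher and 1 lower. A replicate block gave 28 higher and 26 lower, the depth set as a factor 17 and 11, and edgeR with the mouse not modelled 11 and 10. Among the 4 in limma, Acot1 (1.94, adjusted p = 0.0439) and Acadl (adjusted p = 0.0109) rose, and Scd2 fell (-1.58, adjusted p = 0.0175). With 1 value per mouse none of these calls remained: edgeR on counts summed per mouse called 0 of 12717 genes (333 under 0.05) and limma on the mean log2 CPM per mouse 0 of 12339 (246 under 0.05). Without control mouse 2 none stayed called (Acot1 1.91, Acadl 1.28), only 1 did without high fat diet mouse 1 (1.62 and 1.36) or mouse 2 (1.93 and 1.32), and without control mouse 1 the number was 29 with all 4 among them. PPAR targets and fatty acid oxidation were higher by camera (0.48, 3 of 47 called, adjusted p = 3.0e-43 and adjusted p = 0.573 with an estimated correlation), with a median of 0.30 without high fat diet mouse 1. Nuclear-encoded oxidative phosphorylation was lower by camera (-0.15, adjusted p = 9.7e-05 and adjusted p = 0.89 with an estimated correlation).

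Transit-amplifying cells, the dividing daughters of stem cells, also had lipid genes among those called. In the proximal small intestine (2 against 2 mice), Acot1 rose by 5.41 and Creb3l3 by 5.19 (each adjusted p = 8.7e-06). Fabp1 rose by 4.49 (adjusted p = 0.000124) and Me1 by 4.46 (adjusted p = 0.001). Scd2 fell by 3.28 (adjusted p = 0.0175) and the defensin-related AY761184 by 3.19 (adjusted p = 0.0383). edgeR called 26 of 11361 genes, 24 higher and 2 lower (635 at an unadjusted p under 0.05). The mice did not overlap for 37.9% of genes, where 2 of the 6 splits of 4 mice part them by chance. Leaving out any of these 4 mice leaves 1 mouse in a diet, which is then assumed to vary like the other groups. The number called was 50 without control mouse 1, 5 without high fat diet mouse 2 and 9 without high fat diet mouse 3.

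Of the lists in proximal transit-amplifying cells, 4 others rose or fell alongside PPAR targets and fatty acid oxidation (median 1.00, 12 of 48 called, 29 rose over the list alone, adjusted p = 7.3e-77 and adjusted p = 0.0145 with an estimated correlation). Glutathione and xenobiotic defence rose (0.83, adjusted p = 6.8e-23 and adjusted p = 0.0202 with an estimated correlation), as did lipid absorption and chylomicrons (0.26, adjusted p = 6.4e-09 and adjusted p = 0.0145 with an estimated correlation). The defensins fell (-2.85, adjusted p = 3.4e-11 and adjusted p = 0.0324 with an estimated correlation), but not in these cells alone: Defa24 went from 49.1 to 11.2 CPM here, from 41.5 to 11.5 CPM in absorptive-like and from 28.9 to 8.96 CPM in T-like cells. So did the mitochondrially encoded genes, which code for parts of the respiratory chain (-0.74, 7 of 12 fell over the list alone, adjusted p = 1.7e-07 and adjusted p = 0.0313 with an estimated correlation). The mitochondrial gene mt-Co3 had a count in only 12 of the 15 libraries, against all 15 for mt-Co1 and mt-Cytb. Whether mitochondrial genes were counted alike in all libraries was not tested. MHC class II was lower by camera (-1.19, 6 of 7 fell over the list alone, adjusted p = 7.3e-09 and adjusted p = 0.113 with an estimated correlation).

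In distal transit-amplifying cells, edgeR called 6 genes, 5 higher and 1 lower (503 at an unadjusted p under 0.05). Acot1 rose by 3.87 (adjusted p = 0.00349), the serine synthesis gene Phgdh by 2.50 (adjusted p = 0.036) and the Paneth cell lysozyme Lyz1 by 1.90 (adjusted p = 0.0267), which was at 18.3 against 43.4 CPM in distal T-like cells, with overlap between the libraries of the diets. Without control mouse 1 the number was 31, and without control mouse 2 it was 2 with none of the 6 kept. By camera, fatty acid oxidation genes and PPAR targets were higher (0.52, 2 of 48 called, 14 rose over the list alone, adjusted p = 3.3e-25 and adjusted p = 0.116 with an estimated correlation). The mean of the 2 parts gave 27 called genes in limma, 20 higher and 7 lower (745 at an unadjusted p under 0.05). The balance did not hold with a replicate block on the mouse numbers, which called 284 higher and 326 lower. Among the 27 were Acadl (1.41), Slc25a20 (1.68) and, on the lower side, Scd2 (-2.65, adjusted p = 0.00156), the sucrase Sis (-1.95) and the mitochondrial mt-Co1 (-1.44, adjusted p = 0.0189) and mt-Cytb (-0.92). The number called was 2 without high fat diet mouse 2.

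Absorptive cells take up and process dietary lipid. In the proximal small intestine, Mgll rose by 5.99 (adjusted p = 0.00161) and Acot1 by 5.77 (adjusted p = 0.000475). Me1 rose by 5.59 (adjusted p = 1.2e-05) and Acacb, which makes the malonyl coenzyme A that limits fatty acid import, by 4.91 (adjusted p = 0.00431). Scd2 fell by 3.66 (adjusted p = 0.000549; 188 ± 48.2 against 17.0 ± 8.25 CPM), and Tmem252 (-1.61), Akr1c14 (adjusted p = 0.0362) and the transcription factor Tbx3 (-1.44) were lower. edgeR called 42 of 12201 genes, 36 higher and 6 lower (687 at an unadjusted p under 0.05), and the mice did not overlap for 22.4% of genes, where chance gives 20%. Different clusters hold most of these cells in each diet: cluster 17 holds 422 of the 457 control cells and cluster 8 holds 777 of the 835 high fat diet cells. The number called was 84 without control mouse 2, 71 without control mouse 1, 24 without the proximal library of high fat diet mouse 1 and 10 without high fat diet mouse 2.

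PPAR targets and fatty acid oxidation rose in proximal absorptive cells (median 1.03, 12 of 48 called, 33 rose over the list alone, adjusted p = 3.0e-61 and adjusted p = 0.00133 with an estimated correlation). So did glutathione and xenobiotic defence (1.03, 4 of 31 called, 16 rose over the list alone, adjusted p = 3.1e-25 and adjusted p = 0.00133 with an estimated correlation). Lipid absorption and chylomicrons (0.69, adjusted p = 6.0e-09 and adjusted p = 0.275 with an estimated correlation) and cell cycle (0.63, 10 of 39 rose over the list alone, adjusted p = 7.9e-16 and adjusted p = 0.178 with an estimated correlation) were higher by camera only. In distal absorptive cells, edgeR called 2 genes of 12201 (449 at an unadjusted p under 0.05), among them the desaturase Scd1, which fell by 5.26 (44.6 ± 2.46 against 0.803 CPM). Cluster 6 holds 493 of 496 control and 489 of 490 high fat diet cells there. PPAR targets and fatty acid oxidation rose (0.64, 1 of 48 called, 19 rose over the list alone, adjusted p = 2.9e-34 and adjusted p = 0.00702 with an estimated correlation). The number called was 31 without control mouse 1 and 21 without control mouse 2. The mean of the 2 parts gave 49 called genes in limma, 41 higher and 8 lower (916 at an unadjusted p under 0.05), including Creb3l3 (3.44), Akr1b8 (2.66), Ces1f (1.79) and Scd2 (-2.72). The number was 205 without control mouse 1 or 14 without high fat diet mouse 2. With 1 value per mouse, counts summed in edgeR gave 20, and the mean log2 CPM in limma gave 0 of 12201 (649 under 0.05).

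More genes were called between the organs than between the diets in stem-called cells, in tests of unlike power. The organ test compares organs within 5 mice and recovered 81% of simulated 2-fold changes, against 36% and 29% for the proximal and distal diet tests. Between the proximal and distal small intestine, edgeR called 1332 of 11490 genes, 537 higher in the proximal part and 795 lower (2613 at an unadjusted p under 0.05). The transcription factor Onecut2 was higher proximally (6.11, adjusted p = 5.8e-10; 231 against 3.13 CPM), as were Creb3l3 (4.86) and the gastrokine Gkn3 (3.46; 174 against 18.7 CPM). The ileal bile acid carrier Fabp6 (-7.90, adjusted p = 1.2e-07, at 0.416 against 98.0 CPM) and the defensin Defa22 (202 CPM distally) were higher distally. The part of free RNA or of Paneth-like cells with the stem call in such differences was not tested. Against the proximal small intestine, the colon had 3464 called genes, 1752 higher and 1712 lower (4598 at an unadjusted p under 0.05), and against the distal small intestine 2430, 1272 higher and 1158 lower (3656 at an unadjusted p under 0.05). The posterior homeobox gene Hoxb13 was at 72.3 CPM and the carbonic anhydrase Car1 at 200 CPM in the colon, with no count elsewhere. The stem cell gene Olfm4 was at 4806 and 4590 CPM in the proximal and distal small intestine with no count in the colon. Car2 was higher in the colon than distally (7.23, adjusted p = 3.0e-11; 249 against 1.60 CPM). Without high fat diet mouse 3 the proximal to distal number was 840, of which 802 were among the 1332.

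Whether the diet acts differently along the gut was tested with diet by organ interactions in stem-called cells. Acot1 (-2.37, adjusted p = 0.00642) and Retsat (-1.45, adjusted p = 0.0227) responded less in the colon than proximally. Scd2 fell less in the colon than proximally (1.92, adjusted p = 0.0329). Between the proximal and distal parts, the metalloprotease Mmp7 and defensin genes, which are genes of Paneth cells, were among the 10 lower. No gene list was tested in the interactions. edgeR with the mouse as a block called 13 genes proximal against distal (3 higher, 10 lower, 441 at an unadjusted p under 0.05), 6 colon against proximal (518) and 1 colon against distal (476). Without the mouse block, edgeR called 0 in each (178, 215 and 183 of 12339 at an unadjusted p under 0.05), and DESeq2 called 4, 17 and 1. Leaving out control mouse 1 gave 5, 12 and 4 calls, and leaving out high fat diet mouse 2 gave 0 for the colon against proximal test.

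**Figure D3:**
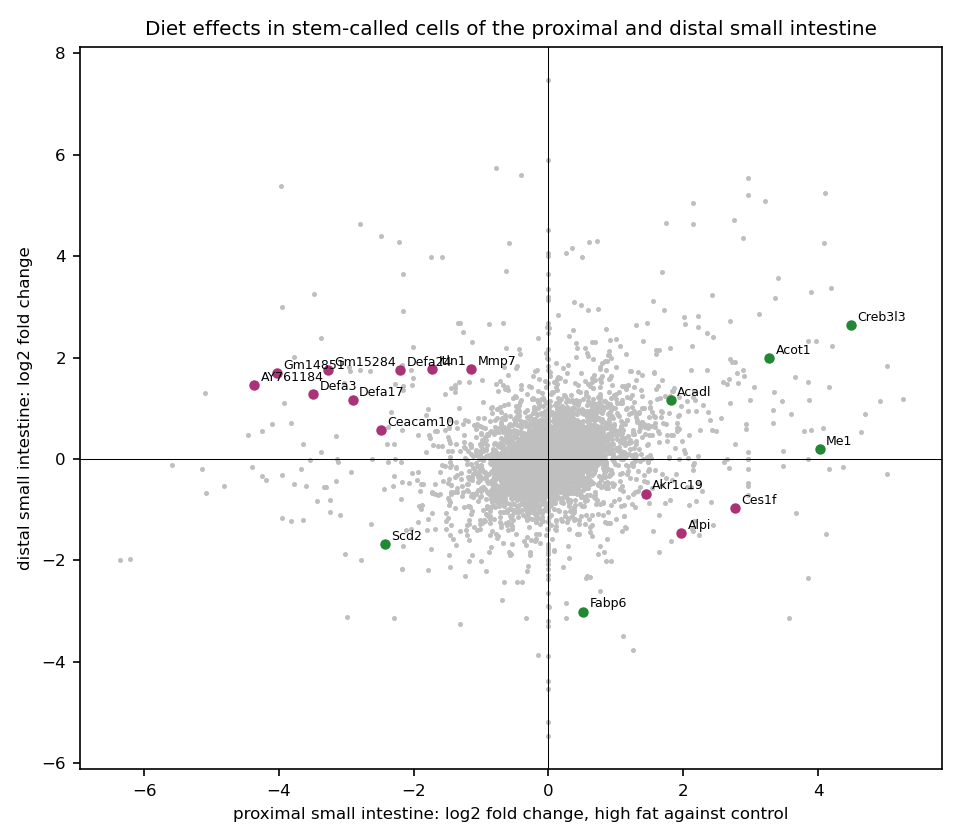
Diet effect on each gene in stem-called cells as log2 fold change, proximal (horizontal) against distal small intestine (vertical); purple points are named genes whose effects differ by the interaction test, green points other named genes, grey points all others. Ceacam10 lies at -2.48 and 0.58, and the defensin genes lie to the left of 0 and above it.

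The share of cells that carry the stem call was lower in every high fat diet mouse than in the control mice in the proximal small intestine. It was 34.5 ± 3.31% in 2 control against 18.3 ± 0.914% in 3 high fat diet mice, a difference of -16.2 points (exact permutation p = 0.1, the smallest that 10 splits allow; adjusted p = 0.3). With cells thinned to 3000 UMIs the shares were 14.7 ± 3.95% and 8.49 ± 1.94% (exact permutation p = 0.1; adjusted p = 0.3), after 2 control and 154 high fat diet cells below that depth were left out. The shares were 28.6 ± 10.2% and 28.8 ± 5.28% distally (exact permutation p = 1) and 15.6 ± 4.34% and 13.6 ± 4.95% in the colon (exact permutation p = 0.6). T and B cells of the same proximal libraries, which should lack Lgr5, carried the call at 22.4% and 33.3% in the control and 11.1%, 28.1% and 23.8% in the high fat diet mice (21 to 49 cells each), so the share is not a measure of stem cell number. The shares of other cell types stay undecided, since 10 splits cannot bring the exact permutation test to a call. edgeR called 0 types in each organ, with 1 at an unadjusted p under 0.05, the Paneth-like cells of the distal small intestine. These were at 0.565 ± 0.275% against 3.17 ± 1.99% (log2 fold change 2.45, p = 0.0241, adjusted p = 0.168; exact permutation p = 0.2). Macrophage, dendritic or granulocyte-like cells were at 0.811% against 0.464% there (exact permutation p = 0.1; adjusted p = 0.467), and B or plasma-like cells in the colon at 2.62 ± 1.98% against 19.5 ± 17.5% (exact permutation p = 0.3; adjusted p = 0.9).

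**Figure D4:**
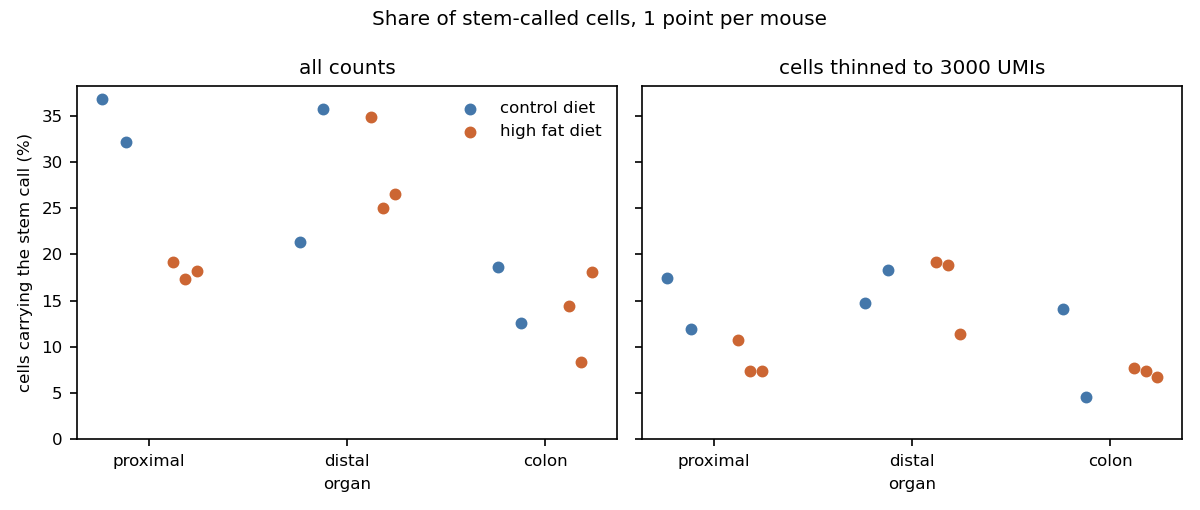
Share of cells carrying the stem call in percent (vertical), with 1 point per mouse, by organ (horizontal) and diet (colour), with all counts (left) and with cells thinned to 3000 UMIs (right). Proximal control mice average 34.5% and high fat diet mice 18.3% with all counts, and the proximal points of the diets do not overlap in either panel.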

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

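Chosen after their results were seen were the tests for the level of free RNA against its source, for sampling nearer the proximal end and for the splits of the libraries. The rule that a level test meets its prediction was also tightened, to ask for a ratio at or below 0 in every library, after the value for the distal genes had been seen, which moved that test from met to undecided. The rule for sampling nearer the proximal end was likewise tightened, to ask for the spread over genes, which moved it from excluded to undecided. Log2 ratios of levels in these tests have 10 CPM added unless stated.

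The results below stand out because the interaction test found the diet's effect to differ between 2 organs in stem-called cells; none of these calls remained when the mouse was not modelled as a block. Proximal against distal, the difference in log2 fold change was -3.09 for the adhesion molecule Ceacam10 (adjusted p = 0.000272; chromosome 7, 24777206 to 24784657; diet effects -2.48 and 0.58), -5.78 for AY761184, -5.77 for Gm14851, -5.11 for Gm15284, -4.06 for Defa17, -3.60 for Defa24 and -4.93 for Defa3, all defensin or defensin-related genes. It was -2.73 for Mmp7 (adjusted p = 0.0117) and -3.06 for the lectin Itln1. It was 2.11 for Akr1c19 (diet effects 1.44 and -0.68), 3.10 for the alkaline phosphatase Alpi (1.97 and -1.47) and 3.71 for the carboxylesterase Ces1f (2.77 and -0.97). Colon against proximal, it was -2.37 for Acot1, 2.17 for Ceacam10, -1.45 for Retsat, 1.92 for Scd2 and -5.71 for the hormone gene Sct. Gm14851 and Defa3 had a count in 9 of the 15 libraries. Since a 0 in a library gives no limit on a level, the sizes of their differences are uncertain.

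The rise of PPAR target and fatty acid oxidation genes in proximal stem-called cells could come from the stem cells or from free RNA of absorptive cells. Free RNA is not excluded: the 7 called genes of the list had a median log2 ratio of stem-called to T-like cells of 0.136 on the high fat diet (libraries -0.257 to 0.883), and of -0.478 to absorptive-like cells (-0.609 to -0.124). Absorptive cells that carry the call are excluded as the whole cause, since the list's median log2 ratio of the diets (10 CPM added) was 0.455 without those 53 cells and 0.486 with them. Values within the depth sets argue against depth as the whole cause, with medians on the same scale of 0.497 in the deeper and 0.568 in the shallower mice. The shallower set is uneven in this organ, at a median of 12040.5 UMIs in control mouse 1 against 4757 and 13640.5 in high fat diet mice 1 and 2. With the proximal library of high fat diet mouse 1 left out, the list's fitted median was 0.591. A response of stem cells to the diet, which the design names, remains open and was not tested apart from free RNA.

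The 10 genes called lower in the proximal against distal interaction, among them Paneth cell genes, had a median difference of -2.90 (10 CPM added, or -3.75 with 0.5). They were chosen by that test, so the median does not support a change of Paneth cell genes as a group. It serves only as the value to set beside that without some of the cells. Within an organ no defensin was called, and the distal rise was not general, at 2.44 in the deeper and -0.60 in the shallower mice (0.5 CPM added). Leaving out the 80 stem-called cells of the Paneth-like cluster, proximal and distal, brought the median difference to -0.509 (-0.76 with 0.5 CPM added). Among the leading genes of that cluster are Gm15284, AY761184, Defa24, Defa17, Itln1 and Gm14851, which are also among the genes tested. Leaving it out would lower their levels whichever cells it holds. The drop therefore does not tell Paneth cells that carry the stem call from stem cells that express these genes. With 0.5 CPM added, Ceacam10, not among those leading genes, was at -2.30 proximally with and -2.31 without those cells. Others kept a part proximally: AY761184 (-4.40 to -1.43), Gm15284 (-3.92 to -1.365), Gm14851 (-4.84 to -1.03) and Defa3 (-3.54 to -0.98). Mmp7 went from -1.25 to -0.11 proximally but only from 1.58 to 1.00 distally, and Defa24 went from -2.43 to -0.38 proximally. The ratio of stem-called to T-like cells was 2.55 in control proximal libraries (2.18 to 2.50 in single libraries). This argues against free RNA from Paneth cells as the whole source of these levels in the sums tested. Those sums include the stem-called cells of the Paneth-like cluster, and the genes were chosen by a test on them. The ratio was not computed without these cells, so free RNA stays open for what remains. Defa24 was lower on the high fat diet in proximal T-like cells too. Whether the diet changes the number of Paneth cells remains open, as their share was not called.

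Genes of the distal small intestine were lower in distal stem-called cells on the high fat diet by camera alone. Sampling nearer the proximal end is undecided: the 1332 genes that differ between the organs moved toward proximal levels by a median of 0.00435 (-0.0121 to 0.0655 in single high fat diet mice), but they went both ways, with quartiles of -0.270 and 0.249. Free RNA of absorptive cells could contribute and is undecided too, with a median ratio of stem-called to T-like cells of -0.0484 over 12 genes in control distal libraries (-0.692 and 0.989). The diet as a direct cause was not tested.

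The differences between organs in stem-called cells were checked against 100 splits of the 10 libraries of each pair of organs. In each pair, 1 split reached the number of called genes, the real one, with 1395 genes proximal against distal, 2844 colon against proximal and 1819 colon against distal in fits of those libraries alone, and at most 114, 0 and 1 in any other split. Of these splits, 14, 13 and 12 part the 2 libraries of every mouse as the real one does, too few for a share under 0.05; the others among them gave 0 calls.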

How the results depend on the processing

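Over all alternatives, 3930 values of named genes kept direction and side of the threshold, 329 were weaker, 29 stronger, 116 moved and 1 reversed. For lists, 1497 kept both, 414 were weaker and 17 reversed. For numbers of called genes, 151 stayed within 1.5 times and 141 moved. In proximal stem-called cells Creb3l3 and Mgll stayed called throughout. On simulated counts edgeR missed most genes changed 2-fold in the proximal and distal diet tests (36% and 29% recovered) and nearly all in the proximal to distal interaction (3%). The mean over organs recovered 90% of them and the colon to proximal organ difference 81%. The simulated libraries were drawn independently, so these rates leave out the correlation between the organs of a mouse and may be too high. The cause of each move was not tested unless stated, and alternatives chosen after seeing the data are marked as added.

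The PPAR list in stem-called cells lost its call with an estimated correlation and with fry in the distal small intestine (median 0.35), the colon (0.10) and the mean (0.48), and in the colon with cells thinned to 1000 UMIs (0.0847, adjusted p = 0.139). Without a filter on low counts, the numbers called were 31 proximal and 3 distal in stem-called, 143 and 96 in transit-amplifying and 168 and 57 in absorptive cells. The interactions gave 38, 29 and 3 (proximal to distal, colon to proximal, colon to distal), from more genes tested. Without doublets, distal stem-called cells gave 2. Cells thinned to 1000 UMIs gave 8 and 2 in stem-called cells, 11 in proximal transit-amplifying cells, 12, 1 and 16 (proximal, distal, mean) in absorptive cells, 257, 669 and 487 for the organs and 2 for the colon to distal interaction. DESeq2 gave 40 and 9, 47 and 12, and 70 and 14 in the 3 populations (proximal and distal). It gave 4 and 17 for the first 2 interactions. limma voom gave 41 and 3, 64 and 12, and 82 and 1. Samples of the organ alone gave 24 and 0 in stem-called cells (246 of 11442 at an unadjusted p under 0.05 in the latter) and 141 in proximal absorptive cells.

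The labels give no reason for mice of different diets to share a number, and the numbers were not taken as pairs. Over 5000 genes, mice of the same label number correlated at 0.033 to 0.463 within the organs, and mice of the same number in the cell table at 0.301 to 0.463. With 2 control mice, whose deviations from their mean mirror each other, and 2 pairs per organ, these values do not decide whether the numbers mark pairs. A replicate block on those numbers gave 49, 9 and 54 called genes (proximal, distal, mean) in stem-called, 182, 70 and 610 in transit-amplifying and 130, 23 and 112 in absorptive cells. Under this block the direction of the test turned for ribosomal proteins in the mean of stem-called cells (median -0.0146). The added block on the cell table's numbers gave 50, 2 and 53, 120, 86 and 595, and 114, 25 and 107, and the test turned for dissociation stress in the mean of transit-amplifying cells (0.39). With no replicate block, the organs gave 709, 2246 and 1590 and the interactions 0, 0 and 0.

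For the mean over organs, counts summed per mouse gave 0, 6 and 20 in the 3 populations, the mean log2 CPM per mouse 0, 13 and 0, and edgeR with the mouse not modelled 21 in stem-called cells. The control diet alone gave 371, 1724 and 993 for the organs and the high fat diet alone 777, 2054 and 1420, from fewer samples. At least 50 cells per sum gave 7 and 2 for the first 2 interactions, from fewer samples.

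Added: the depth set as a factor gave 33, 3 and 28, 53, 19 and 100, and 106, 17 and 156. Genes with a count in all 15 libraries gave 2 in distal stem-called, 17 in the mean of transit-amplifying and 1 in distal absorptive cells and 2 for the proximal to distal interaction, and turned the proximal small intestine list in proximal transit-amplifying cells (-0.17). Stem-like clusters gave 53 proximal calls, 10 of them among the 15, and 2 distal ones, and turned Lgr5 (1.20), the stem cell list (0.39), Wnt targets (0.25) and the distal list (-0.56) proximally and glutathione defence distally (0.0722). These clusters are named by stem cell markers and hold 1441 control but 153 high fat diet cells proximally, so their stem cell and Wnt values decide nothing. The stem call at 3000 UMIs gave 2 in distal stem-called cells, 851, 2168 and 1616 for the organs and 1 and 3 for the first 2 interactions, and turned antimicrobial defence (0.29) and defensins (0.72) proximally.

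With each mouse or, added, the proximal library of high fat diet mouse 1 left out, where a lone control mouse is assumed to vary like the other groups, the numbers called ranged from 4 to 17, 0 to 1, 0 to 1 and 0 to 29 in stem-called cells (proximal, distal, colon, mean). They ranged from 5 to 50, 2 to 31 and 2 to 81 in transit-amplifying and 10 to 84, 2 to 31 and 14 to 205 in absorptive cells. The ranges were 840 to 1192, 2500 to 3410 and 1791 to 2525 for the organs, the upper ends being those without that library (1080, 3207 and 2245 with a whole mouse left out). They were 5 to 21, 0 to 12 and 1 to 4 for the interactions, and 0 to 0 for cell types, where the permutation test cannot reach a call. The PPAR medians ranged from 0.591 (without that library) to 0.942, 0.268 to 0.496, -0.014 to 0.334 and 0.30 to 0.565. The test's direction turned for some lists, given here with their lowest and highest medians. Without control mouse 1 they were cell cycle in distal stem-called (-0.0159, range -0.0159 to 0.495), lipogenesis in distal transit-amplifying (0.0542, range -0.79 to 0.0542) and lipid absorption in distal absorptive cells (0.0978, range 0.0756 to 1.37). Without control mouse 2 they were MHC class II (-0.0339, range -0.0339 to 0.714) and colon (1.80, range -1.04 to 1.80) in colon stem-called cells. The same mouse turned dissociation stress in the mean of transit-amplifying cells (-0.15, range -0.15 to 0.736). It also turned oxidative phosphorylation in distal (0.0641, range -0.284 to 0.0641) and MHC class II in the mean (-0.0896, range -0.866 to -0.0896) of absorptive cells.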

Other observations

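Other cell types, chosen after their values were seen and tested with edgeR in the same way, also had lipid genes among those called. In proximal goblet-like cells, which secrete mucus, 5 of 10083 genes were called: Mgll (4.81), Fabp1 (5.59), Creb3l3 (6.94) and Acadl (1.73) rose and Scd2 fell (-3.33). In proximal enteroendocrine-like cells, which secrete hormones, 8 of 9235 were called, among them Acot1 (2.80), Cpt1a (1.67), Fabp1 (4.98), Creb3l3 (4.23), the lysophospholipase Enpp2 (9.32) and Coro2a (2.89) higher and Scd2 lower (-3.47). PPAR targets and fatty acid oxidation rose in both, by a median of 0.55 (adjusted p = 5.7e-39 and adjusted p = 0.0425 with an estimated correlation) and 0.72 (adjusted p = 1.4e-31 and adjusted p = 0.00917 with an estimated correlation). With 1 mouse or the proximal library of high fat diet mouse 1 left out, the numbers called ranged from 1 to 9 and from 3 to 32.

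T or innate lymphoid-like cells of the proximal small intestine, which are not epithelial, also showed Fabp1 (4.69) and Creb3l3 higher, 2 of the 3 called genes of 6606, and a PPAR list median of 0.81 (adjusted p = 1.2e-39 and adjusted p = 0.0159 with an estimated correlation), against -0.02 distally (adjusted p = 0.488). With 1 mouse or that library left out, 0 to 6 genes were called. The level of Acot1 in the high fat diet proximal libraries was 108 CPM in these cells against 192 in stem-called, 139 in absorptive-like, 116 in transit-amplifying-like and 57.8 in goblet-like cells. Such a level in lymphoid cells could come from free epithelial RNA, for which the ratio of 0.136 between stem-called and T-like cells leaves room. In the distal libraries the level was 45.9 CPM in stem-called and 3.19 CPM in T-like cells. T-like cells pool cluster 20 (median 4172.5 UMIs, 1.52% with the stem call) and cluster 25 (14609.5 UMIs, 28.0%). In high fat diet mice 1 to 3, cluster 25 gave 8, 25 and 21 of 21, 29 and 21 proximal T-like cells. It gave 4, 10 and 15 of 38, 49 and 19 distal ones, so these levels also differ by cluster. T cells caught together with epithelial cells were not tested apart from free RNA.

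In colon deep crypt secretory-like cells edgeR called 0 of 9677 genes (146 at an unadjusted p under 0.05). The PPAR list was higher by camera there (0.18, adjusted p = 0.000786 and adjusted p = 0.472 with an estimated correlation). Of 868 cells of the unnamed cluster 7, 815 came from the proximal library of high fat diet mouse 1. The unnamed cluster 4, led by Acot1 and Angptl4 among others, held 1119 high fat diet and 41 control proximal cells.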
